A study of Mus musculus with 96 samples.

How the data were processed

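Messenger RNA was measured by sequencing in 96 libraries, 47 from sciatic nerve (SCN in the labels) and 49 from gastrocnemius muscle (GASTROC), over 7 regimens of diet and running in male C57BL/6J mice. Per the labels, RNA was extracted with TRIzol, libraries were made with a NEBNext Ultra kit that is not stated to mark the strand, and fragments were read from both ends on a NovaSeq X Plus instrument. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3, MultiQC 1.7 and DESeq2 (no version) and the mouse genome build GRCm38, without a role or an order.

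The deposited files hold 1 log2 value per gene symbol and library. The authors do not state the transform. The library medians (7.46 to 7.66 in nerve, 6.89 to 7.17 in muscle), gene-specific floors and a spread that narrows for low genes resemble those of a regularised log adjusted for library size. If that transform was used, the fold change of a low gene is shrunken toward zero by an unknown amount, which was not tested. The deposited log2 values were used as they stand. Counts and sequencing depth are not in the files, so no counting error could be given. Each tissue was transformed on its own, with 22632 genes in the nerve files and 20940 in the muscle files, and groups were compared within a tissue. Gene positions came from the GENCODE annotation of GRCm38, in which 22054 and 20433 of the symbols were found.

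Groups were taken from the labels: standard diet (SD), high-fat diet (HFD), ketogenic diet (KD), HFD followed by SD (DR), HFD followed by KD (KDI), HFD with a running wheel (EX) and HFD followed by KD with a wheel (KDI_EX). Each library was treated as a separate sample. The labels neither name the mouse behind a library nor tie a nerve to a muscle library, so no paired analysis was possible because the labels give no pairing. Nerve and muscle libraries may come from the same mice, and p-values measure the spread between libraries. No batch is labelled. The highest correlation between libraries was 0.9985 in nerve and 0.9978 in muscle, so no library was a copy of another.

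The comparisons, tests, 38 gene lists, rule for naming genes and most alternatives were chosen before the data were examined. The plan was written for counts, and the tool was changed to limma when the files proved to hold log2 values. Genes with a value of at least log2 of 10 in at least 6 libraries were tested, 17226 in nerve and 15748 in muscle. For each tissue, limma 3.58.1 in R 4.3.3 (with the packages statmod, version 1.5.0, and data.table, version 1.17.8) fitted the 7 groups together with a trended, robust prior variance, and 9 comparisons were drawn from it. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold changes are given on the log2 scale with the standard error from limma, and group levels as mean with standard deviation (SD after a ± sign on a level). The number of libraries showing a direction is the number of libraries of the first-named group beyond the mean of the other group.

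Named genes were, per comparison, up to 8 called genes in each direction with the largest changes (5 in KDI_EX vs KDI, KDI vs DR and the interaction), with a mean log2 value of at least 5.01 in nerve and 5.17 in muscle, group medians that differed by at least 50% of the fitted change, and no placeholder symbol. To these were added up to 4 called members of each called list, and 8 genes in every comparison whatever their p, among them Pdk4, Angptl4, Ucp3, Scd1, Lep and Adipoq. Other called genes are named as chosen after their values were seen. Lists with at least 4 tested members were tested with camera from limma, with a preset correlation between genes of 0.01, and adjusted over all lists and the 9 comparisons of a tissue. The difference of mean list scores was taken again with each library left out in turn, and its smallest value is printed for a reported list where it shrank by over 1.5 times. Members were counted by their adjusted p over all genes and adjusted over the list alone.

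The difference of an effect between tissues was the difference of the limma estimates, with combined standard errors and Satterthwaite degrees of freedom, over 15055 genes tested in both. It sets effects from 2 separately transformed scales against each other, and its standard errors treat the tissues as independent, which does not hold if both came from the same mice. The reversal of HFD changes was measured as Pearson's r across genes between HFD vs SD and each intervention vs HFD. Because both share the HFD libraries, 100 draws of simulated unchanged groups were set beside it. Comparisons were repeated on 100 splits of the libraries into groups of the same sizes. Recovery was tested on simulated data with 200 changed genes and 10 simulations per comparison.

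The alternatives were no filter on low values, library quality weights, marker scores as covariates (adipocyte and skeletal muscle in nerve, adipocyte and slow fibre in muscle), a fit of only the groups compared, and for lists an estimated correlation and fry. A fit of only the groups compared and no filter leave each fold change as it is and move only its error and adjusted p. Chosen after seeing the data were quantile normalisation, leaving out libraries over 2 standard deviations from the tissue mean on the first principal component of 5000 genes, exact permutation of list scores, list scores with single libraries left out, the comparison of KD with HFD, and the pooled comparison of the ketogenic arms. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the reported values.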

Results

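Gene expression was measured in sciatic nerve and gastrocnemius muscle of singly housed male mice that differed in dietary fat and in access to a running wheel. Diets started at 12 weeks of age and tissue was taken at 26 weeks. Fat supplied 10% of energy in the standard diet (SD), 60% in the lard-based high-fat diet (HFD) and 90% in the cocoa butter-based ketogenic diet (KD). Animals on 4 other regimens ate HFD until 18 weeks and then ate SD (DR), ate KD (KDI), kept HFD and gained a wheel (EX), or ate KD and gained a wheel (KDI_EX). Nerve gave 6 SD, 6 HFD, 7 KD, 7 DR, 7 KDI, 7 EX and 7 KDI_EX libraries. Muscle gave 8 SD, 7 HFD, 7 KD, 7 DR, 7 KDI, 7 EX and 6 KDI_EX libraries. Values are deposited log2 expression values, the depth is unknown, and replicates are separate libraries.

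Some dissected samples carried markers of neighbouring tissue. In nerve, the mean centred score of 18 skeletal muscle markers was 0.64 ± 1.52 in SD and -0.50 ± 2.04 in EX (SD, n = 6 and 7), and it reached 4.06 in EX replicate 5 and 4.07 in KDI_EX replicate 7, the nerve libraries that stood apart on the first principal component. In muscle, the score of 20 adipocyte markers ran from -0.39 ± 0.61 in KDI_EX to 0.35 ± 0.49 in EX (n = 6 and 7). The adipocyte score of single nerve libraries ran from -1.03 in KDI_EX replicate 2 to 1.10 in KDI_EX replicate 6.

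**Figure D1:**
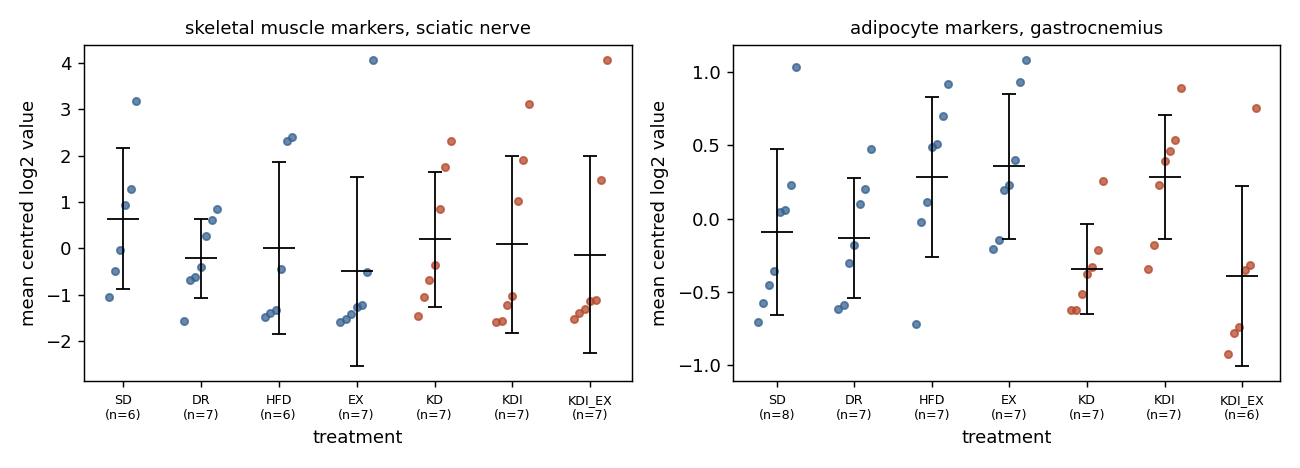
Mean centred log2 value of the skeletal muscle markers in nerve and of the adipocyte markers in muscle, for each library (points) by group, with the mean (line) and SD (bars); red marks groups on KD at the end. The skeletal muscle score of nerve EX replicate 5 lies at 4.06, while the nearest EX library lies at -0.50.

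The effect of the obesogenic diet was addressed by HFD against SD. In muscle, Saa3, an acute-phase serum amyloid (chromosome 7, 46711998 to 46715700), rose by 1.19 ± 0.17 log2 units on HFD. It went from 2.46 ± 0.28 to 3.66 ± 0.63 (n = 8 and 7; adjusted p = 0.000143; higher in 7 of 7 libraries). Saa3 was named as a member of a called list, since no group mean reached the 5.17 asked of genes named by size of change. Its muscle values lay near a floor, at 2.31 ± 0.02 in KD and 2.32 ± 0.01 in KDI_EX. Only HFD and EX held libraries at or above the filter value of log2 of 10. Ucp3, a mitochondrial carrier of skeletal muscle (chromosome 7, 100472990 to 100486432), fell by 0.61 ± 0.12, from 13.10 ± 0.35 to 12.49 ± 0.15 (adjusted p = 0.0367; lower in 7 of 7). Tph2, an enzyme of serotonin synthesis (chromosome 10, 115078641 to 115185022), was the other called gene and was chosen after its values were seen; it rose by 1.68 ± 0.33, from 3.85 ± 0.68 to 5.53 ± 1.17 (adjusted p = 0.0395; higher in 6 of 7). Lep, the adipocyte hormone leptin, had a log2 difference of 1.72 ± 0.48 (adjusted p = 0.218). Pdk4, a kinase that restrains pyruvate oxidation, had -0.60 ± 0.18 (adjusted p = 0.24).

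Of the 29 measured genes of fatty acid beta-oxidation in muscle, 27 had positive changes on HFD, with a median of 0.21. None was called over all genes and 2 rose adjusted over the list alone (Slc25a20 0.35, Ech1 0.50); camera gave adjusted p = 7.18e-09, against adjusted p = 0.697 with an estimated correlation. Among 22 PPAR targets, 1 fell over all genes (Ucp3), while adjusted over the list alone 5 rose, Fabp3 by 0.77 among them, and 2 fell, Ucp3 and Pdk4; camera gave adjusted p = 0.0353, and adjusted p = 0.769 with an estimated correlation. All 12 slow fibre contractile genes were positive (median 0.77, adjusted p = 5.06e-05, and adjusted p = 0.727 with an estimated correlation), as were 16 of 20 adipocyte markers (median 0.40, adjusted p = 0.000142, and adjusted p = 0.73 with an estimated correlation). Of the latter, 3 rose adjusted over the list alone, among them Cidea by 0.90. All 22 myelin genes were negative in muscle (median -0.37, adjusted p = 2.95e-06, and adjusted p = 0.727 with an estimated correlation), and their score difference of -0.34 was -0.22 without SD replicate 6. camera called 21 of 38 lists, 15 up and 6 down, and none with an estimated correlation.

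In nerve, limma called 0 of 17226 genes between HFD and SD (n = 6 and 6), although 3135 had an unadjusted p under 0.05 and 861 were expected by chance. Saa3 had 2.27 ± 0.49 and Tph2 2.53 ± 0.55 (adjusted p = 0.0743 for both). Lep had 1.50 ± 0.58 (adjusted p = 0.2; higher in 5 of 6). Of 56 nuclear genes of oxidative phosphorylation, 6 were positive (median -0.12, adjusted p = 2.43e-05), while 23 of 32 extracellular matrix genes were positive (median 0.13, adjusted p = 0.00607) and the collagens Col4a1 (0.36) and Col4a2 (0.39) rose adjusted over the list alone. Of 20 immediate early genes 2 were positive (median -0.16, adjusted p = 0.00161), and Ier2 fell by 0.49 adjusted over the list alone. All 3 called lists had adjusted p = 0.994 with an estimated correlation.

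The muscle calls of HFD against SD depended on the variance pooled from the other groups. With only SD and HFD libraries fitted, 1 gene was called and the adjusted p was 0.0711 for Saa3 (range over the alternatives 1.53e-05 to 0.0711), 0.11 for Ucp3 (0.00187 to 0.11) and 0.172 for Tph2 (0.00187 to 0.172). With marker scores as covariates the calls of Ucp3 and Tph2 also ended at changes of -0.55 and 1.37 (adjusted p = 0.066 for both), as did that of Tph2 with no filter on low values (adjusted p = 0.0679). With library quality weights 257 genes were called in muscle and 3787 in nerve.

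The long-term ketogenic diet was set against SD. In muscle, 31 genes were called, 11 higher and 20 lower on KD (n = 7 and 8), and each gene named here from these calls was shifted in 7 of 7 KD libraries. Cyp1a1, a xenobiotic-metabolising cytochrome (chromosome 9, 57687928 to 57703824), rose by 1.97 ± 0.24, from 6.20 ± 0.54 to 8.17 ± 0.54 (adjusted p = 1.92e-06). Fbp2, the muscle fructose bisphosphatase of gluconeogenesis (chromosome 13, 62836877 to 62858422), rose by 0.92 ± 0.13 (adjusted p = 4.98e-05). Oxct1, the enzyme that lets tissues use ketone bodies (chromosome 15, 4026383 to 4155344), fell by 0.68 ± 0.10, from 13.35 ± 0.21 to 12.68 ± 0.14 (adjusted p = 2e-04). Slc2a4, the insulin-responsive glucose transporter (chromosome 11, 69942539 to 69948188), fell by 0.43 ± 0.08 (adjusted p = 0.00643).

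Genes of lipid handling moved in both directions in muscle on KD. Acot1, an acyl-CoA thioesterase (chromosome 12, 84009490 to 84018371), rose by 1.31 ± 0.26, from 7.13 ± 0.38 to 8.45 ± 0.52 (adjusted p = 0.00869); it is nearly identical to its neighbour Acot2, and its value can hold reads of that gene. Acadl, a long-chain acyl-CoA dehydrogenase, rose by 0.55 ± 0.12 (adjusted p = 0.0287), and Slc27a1, a fatty acid transporter, by 0.50 ± 0.11 (adjusted p = 0.0261). Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), fell by 1.37 ± 0.29, from 11.01 ± 0.65 to 9.65 ± 0.32 (adjusted p = 0.0189). Impa2 (0.63) and Hoxa4 (0.49) also rose, and Aldh1l1 (-0.63) and Kyat3 (-0.40) fell, with adjusted p from 0.00156 to 0.0475. Ivd fell by 0.51 ± 0.10, Acadsb (chromosome 7, 131410601 to 131448944) fell by 0.47 ± 0.08 and Dbt fell by 0.40 ± 0.07, each an enzyme of branched-chain amino acid breakdown (adjusted p = 0.00982, 0.00115 and 0.00139).

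**Figure D2:**
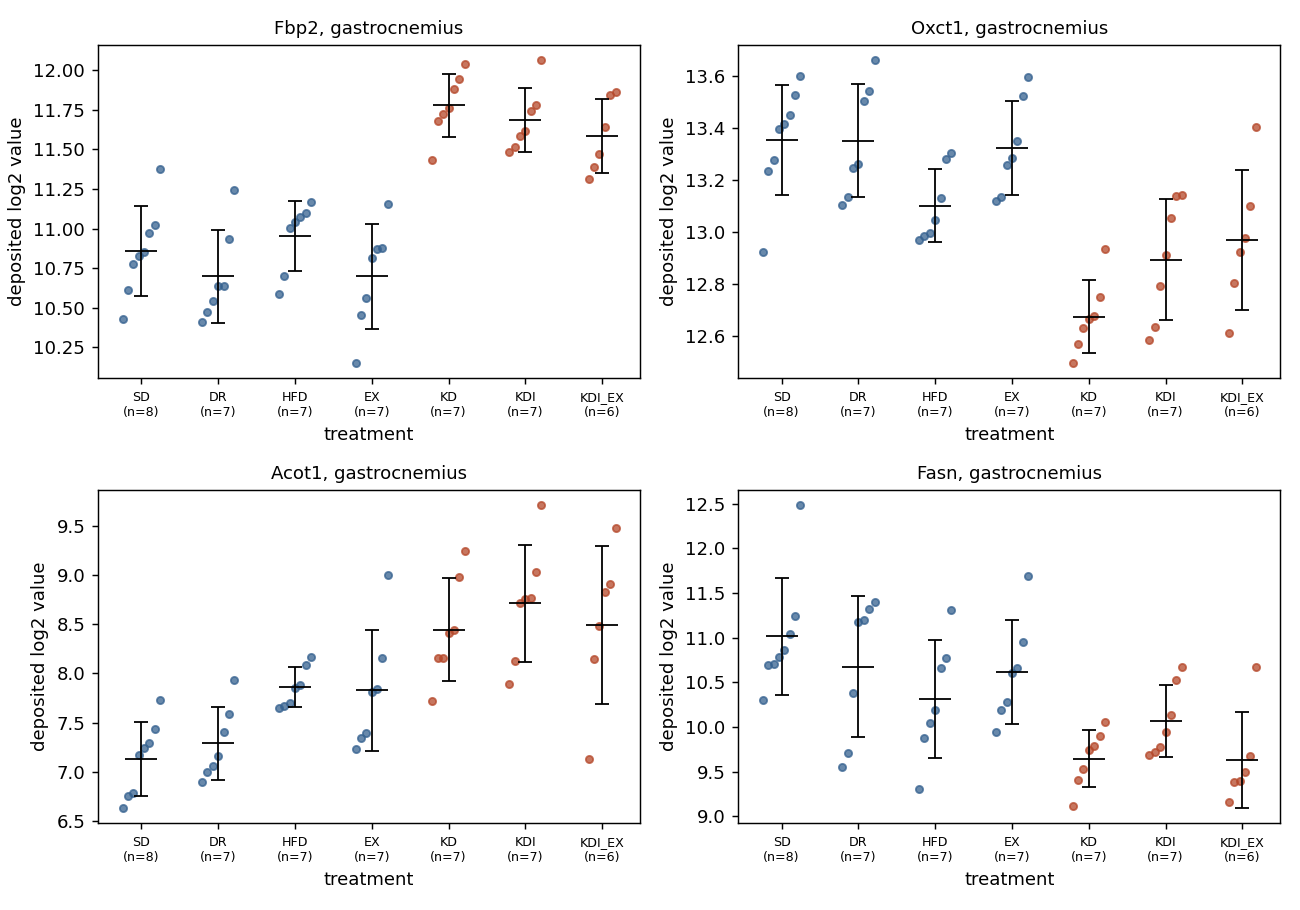
Deposited log2 values of Fbp2, Oxct1, Acot1 and Fasn in gastrocnemius for each library (points) by group, with the mean (line) and SD (bars); red marks groups on KD at the end. Fbp2 lies at 11.78 ± 0.20 in KD and 10.86 ± 0.28 in SD.

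By list, beta-oxidation had 2 of 29 members called, Acadl and Eci2 (0.37 ± 0.08), and adjusted over the list alone 6 rose, Mlycd (0.33) among them, and 1 fell, Ehhadh (-0.31); camera gave adjusted p = 6.97e-05, and adjusted p = 0.733 with an estimated correlation. Among PPAR targets, 1 of 22 rose over all genes (Acot1) and 6 rose and 1 fell adjusted over the list alone, Acot2 by 0.72 and Pex11a by 0.35 (adjusted p = 0.000358, and adjusted p = 0.705 with an estimated correlation). Fatty acid synthesis had 1 of 20 members lower over all genes (Fasn) and 2 adjusted over the list alone, with Acaca at -0.77 (adjusted p = 0.00455, and adjusted p = 0.697 with an estimated correlation). Of 21 genes of the TCA cycle 1 was positive (median -0.12, adjusted p = 0.00118, and adjusted p = 0.769 with an estimated correlation), and of 32 matrix genes 30 were positive (median 0.29, adjusted p = 5.09e-08, and adjusted p = 0.727 with an estimated correlation). The adipocyte score was -0.35 ± 0.31 in KD and -0.09 ± 0.56 in SD muscle. camera called 14 lists, 8 up and 6 down, and none with an estimated correlation.

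In nerve, Cyp1a1 was the gene called on KD, and it was chosen after its values were seen, since its mean level was under the log2 value of 5.01 required of named genes. It rose by 1.58 ± 0.25, from 4.25 ± 0.19 to 5.83 ± 0.72 (n = 6 and 7; adjusted p = 0.00326; higher in 7 of 7). Fasn had -0.93 ± 0.25 (adjusted p = 0.822). Adjusted over the list alone, 6 of 20 genes of fatty acid synthesis fell, Fasn, Acss2 (-0.57), Acly (-0.50) and Me1 (-0.37) among them, and none over all genes (adjusted p = 0.000177). Of 23 macrophage markers 1 was positive (median -0.24, adjusted p = 0.000983). Without SD replicate 5, the score difference changed from -0.27 to -0.17 for fatty acid synthesis and from -0.21 to -0.07 for macrophage markers. camera called 8 nerve lists, 1 up and 7 down, each with adjusted p = 0.994 with an estimated correlation.

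Kyat3 lost its muscle call under quantile normalisation, at -0.42, and without the filter on low values (adjusted p = 0.0662 and 0.0621; range over the alternatives 0.0123 to 0.0662). With only SD and KD libraries fitted, 105 muscle genes were called (223 with library quality weights) and the nerve call of Cyp1a1 ended (adjusted p = 0.805; range 0.000262 to 0.805).

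The return to SD was examined by DR against HFD. In muscle, 4 genes were called, all lower in DR and each in 7 of 7 libraries (n = 7 and 7). Saa3 fell by 1.31 ± 0.18, to 2.35 ± 0.08, near its floor (adjusted p = 3.31e-05). Tph2, chosen after its values were seen, fell by 1.81 ± 0.35 (adjusted p = 0.0313). Oxtr, the oxytocin receptor (chromosome 6, 112473683 to 112489943), fell by 2.02 ± 0.41, from 6.63 ± 1.19 to 4.61 ± 0.33 (adjusted p = 0.046), and Lrg1, a secreted glycoprotein (chromosome 17, 56119678 to 56122001), fell by 0.93 ± 0.19 (adjusted p = 0.046). Ucp3 had 0.51 ± 0.12 (adjusted p = 0.256).

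Myelin genes were higher in DR muscle in 22 of 22 cases (median 0.44, adjusted p = 4.17e-09, and adjusted p = 0.697 with an estimated correlation), and 2 of 29 beta-oxidation genes were positive (median -0.16, adjusted p = 7.18e-09, and adjusted p = 0.697 with an estimated correlation). Of 20 adipocyte markers 3 were positive (median -0.41, adjusted p = 4.4e-07, and adjusted p = 0.697 with an estimated correlation), and Adig (-0.59) and Lep (-1.67) fell adjusted over the list alone. None of 23 macrophage markers was positive (median -0.27, adjusted p = 3.05e-07, and adjusted p = 0.727 with an estimated correlation), and Itgax fell by 0.68 adjusted over the list alone; the score difference of -0.29 was -0.14 without DR replicate 1, which stood apart. Saa3 was the 1 called member of 13 inflammatory cytokines (adjusted p = 0.000108, and adjusted p = 0.624 with an estimated correlation). camera called 16 lists, 2 up and 14 down.

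In nerve, limma called 0 genes in DR against HFD (1271 at an unadjusted p under 0.05; n = 7 and 6), against 44 with library quality weights and 204 with marker scores as covariates. Of 56 nuclear oxidative phosphorylation genes 55 were positive (median 0.14, adjusted p = 2.11e-12), as were 25 of 28 interferon-stimulated genes (median 0.15, adjusted p = 4.25e-06). Of 32 matrix genes 4 were positive (median -0.18, adjusted p = 2.37e-05), and of 24 cell cycle genes 3 (median -0.19, adjusted p = 8.57e-05). The oxidative phosphorylation score difference of 0.13 was 0.05 without DR replicate 2. camera called 9 lists, 6 up and 3 down, each with adjusted p = 0.994 with an estimated correlation. The muscle calls of Oxtr, Lrg1 and Tph2 ended without DR replicate 1 and KDI_EX replicate 6, which stood apart (adjusted p = 0.162, 0.162 and 0.154; ranges over the alternatives 0.00674 to 0.274, 0.000274 to 0.475 and 0.00607 to 0.3). Their changes were then -1.99, -0.90 and -1.77. With library quality weights 54 muscle genes were called. With no filter on low values Oxtr and Lrg1 had an adjusted p of 0.0567. None of the 4 was called when only the HFD and DR libraries were fitted.

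A switch to KD without a wheel was examined by KDI against HFD. In muscle, Cyp1a1 rose by 2.17 ± 0.25 (n = 7 and 7; adjusted p = 3.37e-07), Fbp2 by 0.73 ± 0.13 (adjusted p = 0.0095) and Actc1, the cardiac actin gene (chromosome 2, 114047282 to 114053548), by 1.02 ± 0.20, from 10.32 ± 0.25 to 11.34 ± 0.40 (adjusted p = 0.0265). Actc1 is close in sequence to Acta1, and its value can hold reads of that gene. Saa3 fell by 1.29 ± 0.18 (adjusted p = 2.22e-05) and Tph2 fell by 1.71 ± 0.35 (adjusted p = 0.0325), a pair chosen after their values were seen. These 5 called genes were shifted in 7 of 7 KDI libraries. In nerve, Cyp1a1 rose by 1.87 ± 0.25, from 4.09 ± 0.07 to 5.96 ± 0.64 (n = 6 and 7; adjusted p = 6.76e-05), Tph2 fell by 2.80 ± 0.53 (adjusted p = 0.0226), Saa3 fell by 2.40 ± 0.48, from 6.71 ± 1.74 to 4.32 ± 0.27 (adjusted p = 0.0395), and Cnn2, an actin-binding calponin, fell by 0.25 ± 0.04 (adjusted p = 0.00534), each in 7 of 7. Of the 4, Cyp1a1 and Saa3 were chosen after their values were seen. Cnn2 lay at 11.24 in HFD and 11.09 to 11.10 in SD, KD, DR and EX, so HFD stood apart from these groups too.

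**Figure D3:**
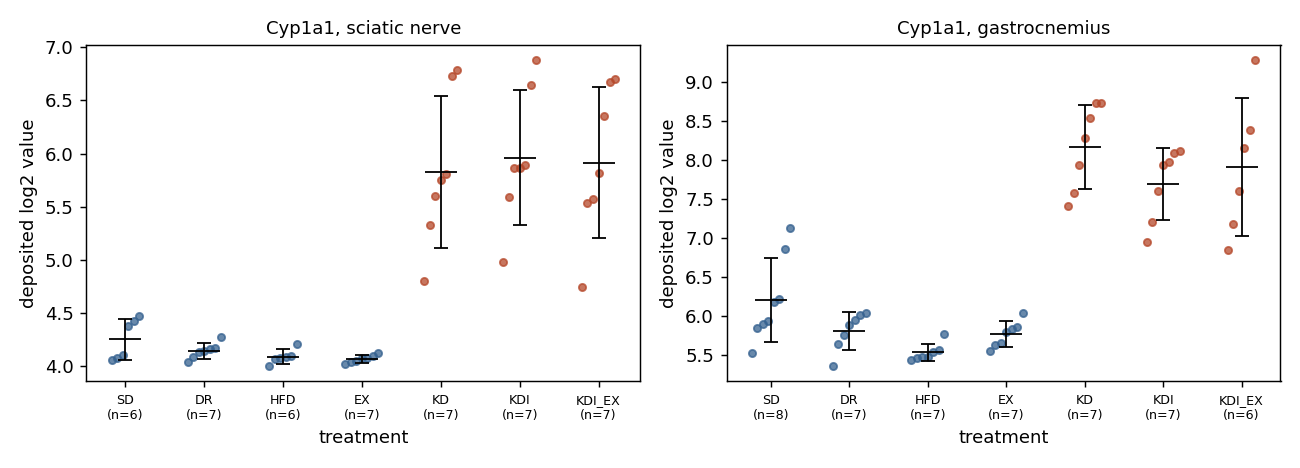
Deposited log2 values of Cyp1a1 in both tissues for each library (points) by group, with the mean (line) and SD (bars); red marks groups on KD at the end. In nerve the groups on KD at the end have means of 5.83, 5.96 and 5.91, and the other 4 have means of 4.07 to 4.25.

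PPAR targets were positive in 19 of 22 cases in KDI muscle (median 0.18, adjusted p = 2.65e-08, and adjusted p = 0.624 with an estimated correlation), and 3 rose adjusted over the list alone, Vnn1 (0.87), Acot1 (0.86) and Acot2 (0.54). Cell cycle genes were positive in 21 of 22 cases (median 0.17, adjusted p = 7.6e-09, and adjusted p = 0.624 with an estimated correlation) and matrix genes in 27 of 32 (median 0.21, adjusted p = 5.37e-06, and adjusted p = 0.733 with an estimated correlation). The cell cycle score difference of 0.19 was 0.05 without KDI replicate 7. In KDI nerve none of 23 macrophage markers was positive (median -0.29, Itgax -0.94; adjusted p = 2.26e-10), 2 of 32 matrix genes were (median -0.20, adjusted p = 1.68e-12) and 3 of 24 cell cycle genes were (median -0.23, Top2a -0.63; adjusted p = 2.08e-09). Of 18 clock genes in nerve, 5 rose and 3 fell adjusted over the list alone, Per2 by 0.34 and Nfil3 at -0.48 (adjusted p = 0.00179). Of 20 adipocyte markers in nerve, Cfd (1.19) and Pck1 (0.92) rose adjusted over the list alone (adjusted p = 0.000781), and the score difference of 0.25 was 0.12 without HFD replicate 3. camera called 14 lists in each tissue, and each nerve list had adjusted p = 0.994 with an estimated correlation.

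With only the HFD and KDI libraries fitted, Tph2 and Saa3 lost their calls in both tissues, and Cnn2 in nerve and Actc1 in muscle lost theirs (Actc1 adjusted p = 0.0528; range over the alternatives 0.00759 to 0.0528). Over the alternatives the nerve adjusted p ranged from 0.00013 to 0.437 for Tph2, from 0.00149 to 0.499 for Saa3 and from 0.00013 to 0.181 for Cnn2, and the muscle adjusted p from 0.00287 to 0.706 for Tph2 and from 3.67e-07 to 0.0738 for Saa3. With no filter on low values Saa3 lost its nerve call and Tph2 its muscle call (adjusted p = 0.0619 and 0.0553). With marker scores as covariates 208 nerve and 24 muscle genes were called. The fit of all 7 groups pools their spread, which was unequal in both tissues. In nerve Tph2 had a standard deviation of 1.79 in HFD and 0.11 in KD, and Saa3 one of 1.74 and 0.10. In muscle it was 1.172 and 0.085 for Tph2, and 0.632 and 0.016 for Saa3. The printed errors of these genes therefore understate the spread of HFD in both tissues. The lowest nerve HFD libraries, at 4.85 for Tph2 and 4.18 for Saa3, lay within the range of KDI (4.82 to 6.23 and 3.97 to 4.72).

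Running on HFD was examined by EX against HFD. In muscle, 31 of 32 matrix genes were positive (median 0.23, adjusted p = 1.51e-06, and adjusted p = 0.73 with an estimated correlation), 2 of 15 fast fibre contractile genes were positive (median -0.16, adjusted p = 0.00137, and adjusted p = 0.713 with an estimated correlation) and none of 12 keratinocyte markers was (median -0.85, adjusted p = 1.22e-06, and adjusted p = 0.697 with an estimated correlation). The keratinocyte scores of HFD replicates 6 and 7 were 3.82 and 2.26, while the other 5 HFD libraries lay at -0.45 to -0.29, and the score difference of -0.81 was -0.27 without replicate 6. In nerve, 18 of 20 adipocyte markers were positive (median 0.49, Cfd 0.76; adjusted p = 5.25e-05) and 1 of 22 myelin genes was (median -0.16, Drp2 -0.24, Ndrg1 -0.21; adjusted p = 4.22e-07), each with adjusted p = 0.994 with an estimated correlation. The mean myelin score was -0.49 in EX replicate 5, which stood apart, and without it the difference between the groups changed from -0.14 to -0.08 (adjusted p = 0.00229 without the nerve libraries that stood apart). No member of these lists was called over all genes or adjusted over the list alone. limma called 0 genes in muscle (318 at an unadjusted p under 0.05; n = 7 and 7) and 0 in nerve (1235; n = 7 and 6), but 857 in nerve with library quality weights. In simulated data of these comparisons with 200 changed genes, 78.2% of changes of log2 0.5 were recovered in muscle and 83.6% in nerve. For changes of log2 0.25 it was 25.8% and 37%. The adjusted threshold is stricter where fewer genes change, so these shares do not say which changes the real comparisons could detect. camera called 10 lists in nerve, 6 up and 4 down, and 14 in muscle, 3 up and 11 down.

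The combined switch and wheel were examined by KDI_EX against HFD. In muscle, 17 genes were called, 7 higher and 10 lower (n = 6 and 7), and those named here were shifted in 6 of 6 KDI_EX libraries. Cyp1a1 rose by 2.38 ± 0.26 (adjusted p = 6.73e-08) and Actc1 by 1.59 ± 0.21, to 11.91 ± 0.34 (adjusted p = 8.96e-06). Fbp2 rose by 0.63 ± 0.14 (adjusted p = 0.0467), Kcnab1, a potassium channel subunit, by 0.61 ± 0.12 (adjusted p = 0.014), the kinase gene Stk26 by 0.53 ± 0.12 (adjusted p = 0.0488) and Hoxa4 by 0.43 ± 0.09 (adjusted p = 0.0305). Lep fell by 2.53 ± 0.52, from 10.76 ± 1.09 to 8.23 ± 0.95 (adjusted p = 0.0219), and Hp, the haemoglobin scavenger haptoglobin (chromosome 8, 109575128 to 109579172), fell by 2.47 ± 0.43, from 12.03 ± 1.13 to 9.56 ± 0.71 (adjusted p = 0.00322). Oxtr fell by 2.09 ± 0.42 (adjusted p = 0.0219), Lrg1 fell by 0.92 ± 0.20 (adjusted p = 0.0324) and Saa3 fell by 1.34 ± 0.18 (adjusted p = 1.74e-05). Foxo6os, annotated antisense to Foxo6, fell by 0.61 ± 0.14 (adjusted p = 0.0488), and reads of either strand can have been counted for it.

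The adipocyte score was -0.39 ± 0.61 in KDI_EX and 0.28 ± 0.55 in HFD muscle. Of 20 adipocyte markers, 1 fell over all genes (Lep) and 9 fell adjusted over the list alone, among them Cidec (-1.60) and Adipoq (-1.38) (median -0.49, adjusted p = 1.66e-11, and adjusted p = 0.624 with an estimated correlation). None of 12 slow fibre genes was positive (median -0.56, adjusted p = 0.000416, and adjusted p = 0.733 with an estimated correlation), and keratinocyte markers had a median of -1.05 (adjusted p = 3.39e-06, and adjusted p = 0.697 with an estimated correlation). Their score difference of -1.03 was -0.49 without HFD replicate 6, and that of the slow fibre genes changed from -0.58 to -0.19 without KDI_EX replicate 5. Of 13 inflammatory cytokines, 1 fell over all genes (Saa3) and 2 adjusted over the list alone, with Ccl8 at -0.76 (adjusted p = 0.0191, and adjusted p = 0.727 with an estimated correlation). camera called 16 muscle lists, 1 up and 15 down.

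In nerve, 12 genes were called in KDI_EX against HFD, 7 higher and 5 lower (n = 7 and 6), and those named here were shifted in 7 of 7 KDI_EX libraries. Cfd, the adipocyte serine protease adipsin (chromosome 10, 79890853 to 79892655), rose by 1.40 ± 0.30, from 13.24 ± 0.35 to 14.63 ± 0.88 (adjusted p = 0.0424). Unc93a2 rose by 1.09 ± 0.20, and Adgrg2, an adhesion G protein-coupled receptor, rose from 7.43 ± 0.22 to 8.43 ± 0.63 (adjusted p = 0.00968 for both). Negr1, a neuronal adhesion molecule, rose by 0.50 ± 0.10 (adjusted p = 0.0135), Gstt2, a glutathione transferase, by 0.46 ± 0.10 (adjusted p = 0.0424), and Cyp1a1, chosen after its values were seen, by 1.82 ± 0.25 (adjusted p = 0.000124). Tph2 fell by 2.74 ± 0.53 (adjusted p = 0.0132), Serpina3n, a protease inhibitor with close paralogs, fell by 0.61 ± 0.11 (adjusted p = 0.0106), Lox, a collagen cross-linking enzyme, fell by 0.36 ± 0.08 (adjusted p = 0.0424) and Cnn2 fell by 0.23 ± 0.04 (adjusted p = 0.00968). HFD had the lowest group mean for Cfd and Adgrg2. Cfd lay at 14.32 in SD and 14.61 in DR, near KDI_EX. Adgrg2 lay at 8.02 in SD and 8.07 in DR, between HFD and KDI_EX. For both genes EX lay between HFD and SD. Serpina3n lay at 12.16 in SD and 12.22 in DR, but at 12.62 in EX, near HFD. The differences of Cfd, Adgrg2 and Serpina3n therefore cannot be ascribed to KD and the wheel alone.

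All 11 mast cell markers were positive in KDI_EX nerve (median 0.29, adjusted p = 3.26e-06), and 2 of 24 cell cycle genes were (median -0.24, adjusted p = 5.88e-08), with Bub1b lower by list alone (-0.43). Of 20 adipocyte markers, 1 rose over all genes (Cfd) and 3 adjusted over the list alone, with Pck1 at 1.01 and Adig at 0.74 (adjusted p = 0.0111), while the score difference of 0.24 was 0.06 without KDI_EX replicate 6. Of 18 clock genes, 4 rose, Dbp (0.65) and Nr1d1 (0.41) among them, and 3 fell, Arntl (-0.40) among them, adjusted over the list alone (adjusted p = 0.0488). Lox was the 1 called member of 32 matrix genes (median -0.09, adjusted p = 0.000208), and their score difference of -0.14 was -0.09 without KDI_EX replicate 5. camera called 13 nerve lists, 6 up and 7 down, each with adjusted p = 0.994 with an estimated correlation.

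None of the nerve calls was made when only the HFD and KDI_EX libraries were fitted, and 2 of the muscle calls were. Without EX replicate 5 and KDI_EX replicate 7, which stood apart, the nerve calls of Cfd (92.9% of its change kept), Negr1 (now 0.46) and Lox (now -0.37) ended (adjusted p = 0.145, 0.0655 and 0.0703; ranges over the alternatives 0.000579 to 1, 0.00256 to 1 and 0.00838 to 0.934), and without DR replicate 1 and KDI_EX replicate 6 the muscle count was 36. Cfd, Gstt2 and Lox also lost their nerve calls with no filter on low values (adjusted p = 0.0558, 0.0541 and 0.0541; range for Gstt2 0.00818 to 1), and Lox and Cnn2 with library quality weights, at -0.36 and -0.17 (adjusted p = 0.0578 and 0.0675; range for Cnn2 0.000522 to 0.934). Kcnab1 and Hoxa4 kept their muscle calls in 3 of the 6 alternatives each (adjusted p 0.0178 to 0.319 and 0.00532 to 0.637), as did Lrg1. With marker scores as covariates Kcnab1 was at 0.50, Hoxa4 at 0.36, Fbp2 at 0.47, Stk26 at 0.33 and Foxo6os at -0.46, and 137 nerve genes were called. Fbp2 kept its muscle call in 2 of the 6 alternatives (adjusted p 0.0194 to 0.25), Stk26 and Foxo6os lost their muscle calls in all 6 alternatives (adjusted p 0.063 to 0.637 and 0.0533 to 0.359), and with marker scores as covariates Lrg1 was at -0.44 and Oxtr at -1.26, without a call (adjusted p = 0.117 and 0.148; ranges 0.0263 to 0.637 and 0.0194 to 0.376). With these covariates Lep was at -1.33 and Hp at -1.40, both still called (adjusted p = 0.0044 and 0.000122; ranges 0.0044 to 0.245 and 0.000122 to 0.245). Lep lost its call with library quality weights, at -2.25, and with only the groups compared (adjusted p = 0.0724 and 0.245), and Hp with only the groups compared (adjusted p = 0.245).

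**Figure D4:**
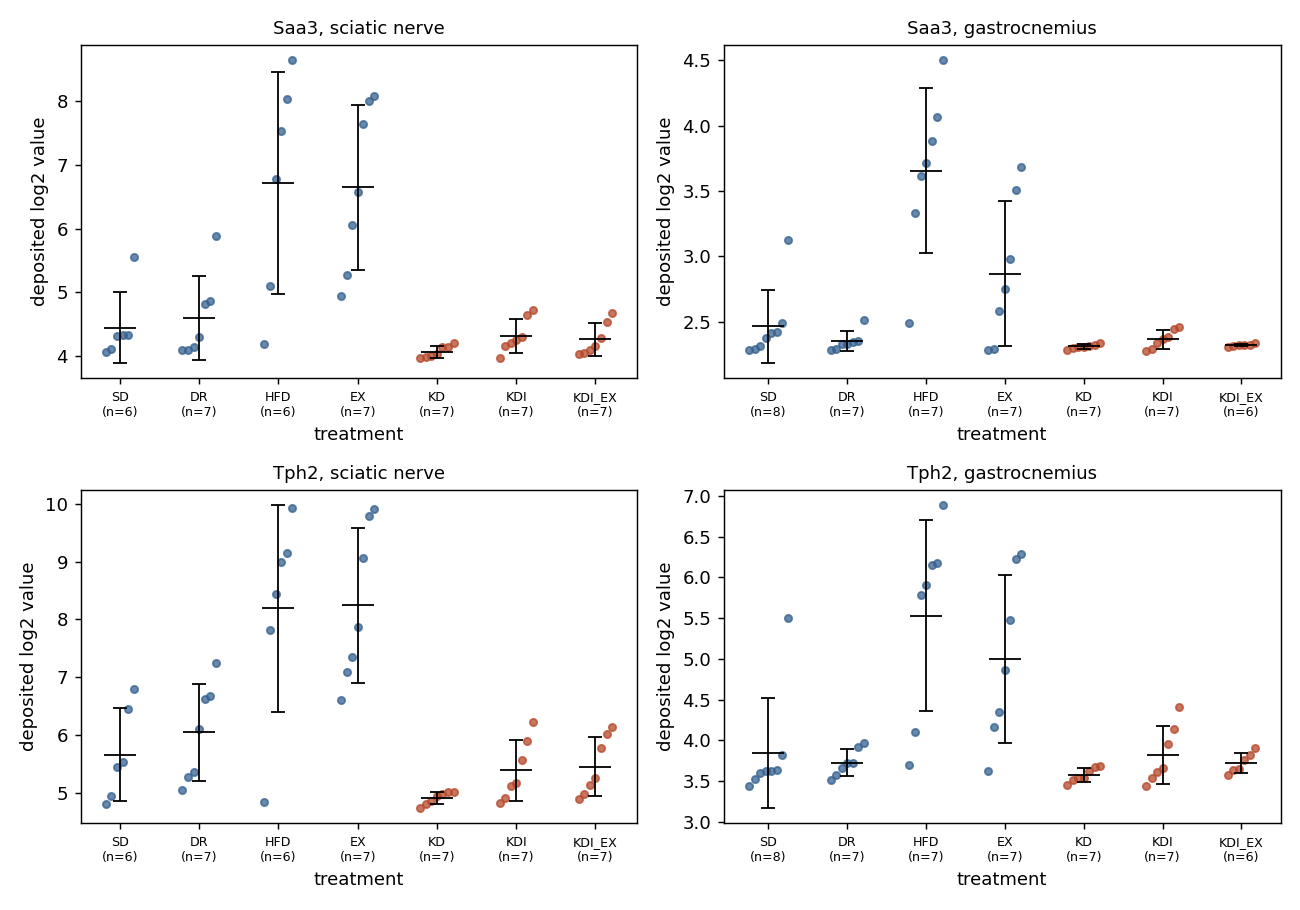
Deposited log2 values of Saa3 and Tph2 in both tissues for each library (points) by group, with the mean (line) and SD (bars); red marks groups on KD at the end. In nerve Tph2 lies at 8.19 ± 1.79 in HFD, 5.39 ± 0.53 in KDI and 5.46 ± 0.51 in KDI_EX.

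The addition of a wheel to KD was examined by KDI_EX against KDI. In nerve, all 11 mast cell markers were positive (median 0.54) and 8 rose adjusted over the list alone, Cpa3 (0.75), Tpsb2 (0.69) and Mrgprb2 (0.54) among them (adjusted p = 2.72e-13). All 23 macrophage markers were positive (median 0.37, adjusted p = 1.68e-12), and none of 22 myelin genes was (median -0.16, adjusted p = 9.01e-10), each with adjusted p = 0.994 with an estimated correlation. The lower myelin score rested on few libraries: it was -0.61 in KDI_EX replicate 6, and the difference between the groups of -0.15 was -0.07 without that library and -0.01 without replicate 7 as well. In muscle, 10 of 20 adipocyte markers fell adjusted over the list alone, with Plin1 at -1.15 (median -0.72, adjusted p = 1.22e-13, and adjusted p = 0.624 with an estimated correlation), while Lep had -1.59 ± 0.52 and Adipoq -1.17 ± 0.41 (adjusted p = 0.977 over all genes; n = 6 and 7). Cell cycle genes had a median of -0.20, and Cdk1 fell by 0.52 adjusted over the list alone (adjusted p = 4.17e-09, and adjusted p = 0.624 with an estimated correlation). Their score difference of -0.24 was -0.10 without KDI replicate 7. limma called 0 genes in nerve (801 at an unadjusted p under 0.05) and 0 in muscle (744), and camera called 11 and 17 lists.

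The diets that followed HFD were compared by KDI against DR. In muscle, Cyp1a1 rose by 1.89 ± 0.25 (n = 7 and 7; adjusted p = 1.42e-05), Acot1 by 1.42 ± 0.27, from 7.29 ± 0.37 to 8.72 ± 0.59 (adjusted p = 0.0113), Fbp2 by 0.99 ± 0.13 (adjusted p = 2.05e-05), Slc27a1 by 0.59 ± 0.11 (adjusted p = 0.0121), Cat, the peroxisomal catalase, by 0.49 ± 0.10 (adjusted p = 0.0173) and Eci2 by 0.45 ± 0.09 (adjusted p = 0.0121), each in 7 of 7 libraries. limma called 8 genes, 7 higher and 1 lower. Of 29 beta-oxidation genes 28 were positive; 1 rose over all genes and 8 adjusted over the list alone, Ech1 (0.67), Acadl (0.52) and Slc25a20 (0.40) among them (median 0.22, adjusted p = 2.22e-14, and adjusted p = 0.624 with an estimated correlation). Of 22 PPAR targets, 1 rose over all genes and 11 adjusted over the list alone, with Fabp3 at 0.82 and Acot2 at 0.77 (adjusted p = 2.05e-10, and adjusted p = 0.624 with an estimated correlation). Adjusted over the list alone, 11 of 32 matrix genes rose, Col1a1 (0.73) and Col6a3 (0.46) among them (adjusted p = 3.44e-14, and adjusted p = 0.632 with an estimated correlation), and 8 of 22 cell cycle genes rose, Top2a (0.77), Ccna2 (0.61) and Cdk1 (0.60) among them (adjusted p = 1.59e-10, and adjusted p = 0.624 with an estimated correlation). The cell cycle score difference of 0.29 was 0.15 without KDI replicate 7. All 20 adipocyte markers were positive (median 0.42, adjusted p = 3.97e-06, and adjusted p = 0.705 with an estimated correlation).

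In nerve, Cyp1a1 was the called gene of KDI against DR and was chosen after its values were seen; it rose by 1.82 ± 0.24 (n = 7 and 7; adjusted p = 5.25e-05; higher in 7 of 7). None of 56 nuclear oxidative phosphorylation genes was positive (median -0.13, adjusted p = 2.72e-13), 7 of 11 mast cell markers fell adjusted over the list alone, Cpa3 at -0.60 and Ms4a2 at -0.49 (adjusted p = 8.52e-08), and macrophage markers had a median of -0.27 (adjusted p = 5.25e-05), each with adjusted p = 0.994 with an estimated correlation. Without DR replicate 2, the nerve score difference changed from -0.13 to -0.04 for oxidative phosphorylation and from -0.23 to -0.16 for macrophage markers. camera called 11 lists in nerve and 15 in muscle. The muscle calls of Acot1, Slc27a1, Cat and Eci2 ended when only the KDI and DR libraries were fitted (adjusted p = 0.0533, 0.0533, 0.12 and 0.105; ranges over the alternatives 9.53e-07 to 0.0533, 0.00297 to 0.0533, 0.000208 to 0.12 and 0.000375 to 0.105), and that of Cat also without DR replicate 1 and KDI_EX replicate 6, at 0.48 (adjusted p = 0.0577). With library quality weights 197 muscle genes were called.

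Whether the wheel acted differently on KD and on HFD was tested as an interaction. In nerve no adipocyte marker had a positive term (20 markers, median -0.51, adjusted p = 1.63e-05), while macrophage markers (median 0.24, adjusted p = 0.000682) and mast cell markers (median 0.31, adjusted p = 0.000308) had positive medians, each with adjusted p = 0.994 with an estimated correlation. The adipocyte term of the scores changed from -0.45 to -0.27 without KDI_EX replicate 2, and the macrophage term from 0.24 to 0.11 without EX replicate 6. In muscle, adipocyte markers had a median of -0.75 (adjusted p = 3.05e-09, and adjusted p = 0.661 with an estimated correlation) and matrix genes of -0.43 (adjusted p = 1.18e-11, and adjusted p = 0.697 with an estimated correlation). limma called 0 genes in nerve (361 at an unadjusted p under 0.05) and 0 in muscle (522). camera called 5 and 12 lists.

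Whether interventions moved genes back toward SD was asked next. In muscle, Saa3 and Tph2 were called higher on HFD than on SD and called lower than on HFD in DR, KDI and KDI_EX. These were the 2 genes called in opposite directions in each of these pairs. Independent calls would give at most 0.00127 genes in a direction, but both comparisons use the same HFD libraries, whose high values alone push the calls apart, and this was not tested for these genes. Across genes, which are not independent replicates, r between the HFD effect and the DR effect was -0.794 in muscle and -0.622 in nerve. Simulated unchanged groups gave mean r of -0.464 and -0.518, because the HFD libraries are shared, and 8 and 19 of 100 draws had a covariance as low. In muscle r was -0.276 for KDI (simulated -0.512), -0.309 for EX (-0.501) and -0.622 for KDI_EX (-0.45). In nerve r was -0.53 for KDI (simulated -0.536), -0.419 for EX (-0.51) and -0.512 for KDI_EX (-0.466). With the HFD libraries split so that each effect used its own, r in muscle was -0.336 for DR, 0.0721 for KDI, 0.0681 for EX and -0.256 for KDI_EX, and in nerve -0.196, -0.124, -0.0573 and -0.13.

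The same contrasts were compared between tissues, whose values were transformed separately, so a difference of effects can also hold a difference of scale. On KD against SD, Oxct1 fell by 0.68 in muscle and had -0.07 in nerve, a difference of 0.61 (adjusted p = 0.0361), and Acadsb had -0.47 and 0.05, a difference of 0.52 (adjusted p = 0.0361). Sctr, the secretin receptor, had 0.80 in nerve and -0.32 in muscle in KDI_EX against HFD, a difference of 1.12 (adjusted p = 0.0265). The predicted gene Gm11837 had -0.38 in nerve and 0.23 in muscle on HFD against SD, a difference of -0.60 (adjusted p = 0.0135). Sctr and Gm11837 were chosen after their values were seen. Acot1 on KD differed by -1.3 (adjusted p = 0.093), and Cyp1a1 by -0.40 (adjusted p = 0.652). Of Pdk4, Angptl4, Ucp3, Scd1, Lep and Adipoq, which were examined in every comparison, Ucp3 and Lep were called in the 9 planned comparisons, each in muscle and in the comparison named above. Of 15055 genes, limma estimates differed for 1 in HFD vs SD, 2 in KD vs SD, 0 in DR vs HFD (759 at an unadjusted p under 0.05), 0 in KDI vs HFD (329), 0 in EX vs HFD (574) and 1 in KDI_EX vs HFD. With library quality weights, 3072 genes differed in HFD vs SD and 963 in EX vs HFD.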

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

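The tests on fat tissue, on a diet effect in both tissues and on receptor targets were chosen only after the results were seen. The predictions for macrophages, other cells and the splits were written before. The macrophage test still concerns genes picked from the calls. The test on other cells and the splits of the pooled ketogenic arms use a comparison chosen after the results were seen.

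Saa3 and Tph2 were higher on HFD than on SD in muscle, and in nerve by 2.27 and 2.53 without a call. With the macrophage score as a covariate Saa3 kept 97.7% and Tph2 97.4% of the change, with Tph2 still called (adjusted p = 0.0471). This met the bound set against more macrophages in the samples. The score overlapped between the groups, at -0.515 to 0.599 in HFD and -0.557 to 1.07 in SD muscle. Adjusting for so small a difference can move few changes, so the test does not decide the question. With adipocyte and slow fibre scores as covariates Saa3 kept 83.2% (1.19 ± 0.17 became 0.99 ± 0.15, adjusted p = 0.00058), which met the bound set against more fat tissue. That bound cannot decide the question. Lep, itself an adipocyte marker, also kept its call with these covariates in muscle on KD against HFD (-2.50 became -1.39, adjusted p = 0.00166). More fat tissue therefore stays open for Saa3. It stays open for Tph2 as well, which kept 81.2% while its call ended. The change of Tph2 fell from 1.68 ± 0.33 to 1.37 ± 0.31 with little change in its error (adjusted p = 0.066, range over the alternatives 0.00187 to 0.172). The genes were judged apart only after this was seen. A diet effect that both tissues show may account for the pattern, the smaller nerve change being 2.27, but the nerve changes did not pass the threshold and it remains a hypothesis. The nerve samples also carried adipocyte transcripts (Adipoq 13.54 in HFD), so agreement of the tissues cannot tell which cells hold the change. The nerve adipocyte score overlapped between HFD (-0.854 to 0.413) and SD (-0.74 to 0.403).

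Cyp1a1 was higher in the ketogenic arms of both tissues, by 1.76 ± 0.13 in nerve and 2.10 ± 0.13 in muscle when these arms were pooled. With endothelial, keratinocyte and adipocyte scores as covariates 93.1% of the change stayed in nerve (1.64 ± 0.12) and 98.8% in muscle. This met the bound set against more endothelial, skin or fat cells. The bound was not checked on a gene known to come from these cells, so it does not decide the question. Activation of the aryl hydrocarbon receptor stays open: the score of 8 other targets in nerve was lower by -0.07 (permutation p = 0.0207) and that of 7 in muscle differed by -0.07 (permutation p = 0.295). The nerve value met the bound set against the explanation, but it was put aside as deciding nothing because the members went both ways, Ahrr at 0.18 and Ugt1a6b, which shares exons with Ugt1a6a, at -0.60. A compound in the cocoa butter diet was not tested and cannot be separated from the fat content by these groups.

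Nerve HFD against SD had 0 called genes by limma (3135 at an unadjusted p under 0.05), yet 3787 with library quality weights and 549 with marker scores as covariates. With weights, 3 of 100 splits of the libraries called as many, the highest other split calling 4233; with covariates it was 2 of 100, the highest other 1028. Another split called more genes under each setting, so chance cannot be excluded for either. Such splits may reflect a structure of the samples, which no label names. No biological explanation was tested.

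Other splits of the libraries, 100 per comparison with the real one included, were counted for every number of called genes. In muscle, no other split called as many genes for KD vs SD (1 split as large, 31 genes, highest other 1), DR vs HFD (1, 4 genes, highest other 0) and KDI vs DR (1, 8 genes, highest other 1). Chance is unlikely for these counts taken singly, though 18 gene counts were tested. For HFD vs SD (2, 3 genes, highest other 22) and KDI vs HFD (2, 5 genes, highest other 5) another split called as many or more, so chance remains possible. It cannot be excluded for KDI_EX vs HFD (5; 17 genes, highest other 3051), and the splits say nothing about chance for EX vs HFD, KDI_EX vs KDI and the interaction, where the real count was 0 and all 100 splits are as large by construction (highest other 19, 3175 and 159). In nerve, another split called as many genes or more for KDI vs HFD (2, 4 genes, highest other 10) and KDI vs DR (2, 1 gene, highest other 1). Chance therefore cannot be excluded for either count. Nor can it be for the counts of KD vs SD (6, 1 gene, highest other 13) and KDI_EX vs HFD (9, 12 genes, highest other 3704). A count does not measure how far a single gene was separated. Cyp1a1, the called gene of nerve KD vs SD and KDI vs DR, was at least 4.74 in every ketogenic nerve library. It was at most 4.47 in every nerve library of the other groups. Again nothing can be said for the comparisons with a count of 0, each at 100 of 100 by construction: HFD vs SD (highest other 41), DR vs HFD (1966), EX vs HFD (404), KDI_EX vs KDI (1695) and the interaction (1). The splits with the highest counts, such as 3704 against a real count of 12, called far more genes than the real split, for a reason that was not tested.

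The number of called lists, adjusted within a comparison for this purpose, was highest in the real split of muscle HFD vs SD (1 of 100; 24 lists, highest other 23). By that count alone the real split stood out there. The margin was 1 list, and this was the 1 of 18 list counts with under 5 of 100 splits as large (7 of 18 gene counts had). No list of that comparison was called with an estimated correlation, fry or permutation, so chance cannot be excluded. It cannot be in muscle KD vs SD (52; 12 lists, highest other 21), DR vs HFD (36; 16, 23), KDI vs HFD (64; 14, 25), EX vs HFD (45; 14, 23), KDI_EX vs HFD (32; 16, 25), KDI_EX vs KDI (24; 18, 25), KDI vs DR (58; 15, 28) and the interaction (62; 12, 24). Nor can it be in nerve HFD vs SD (98; 3, 19), KD vs SD (98; 5, 24), DR vs HFD (65; 9, 19), KDI vs HFD (22; 16, 23), EX vs HFD (80; 11, 23), KDI_EX vs HFD (49; 14, 23), KDI_EX vs KDI (64; 11, 21), KDI vs DR (64; 11, 20) and the interaction (96; 5, 23). For differences between tissues, another split called as many genes in KD vs SD (2, 2 genes, highest other 2), so chance cannot be excluded there. It cannot be in HFD vs SD (5; 1 gene, highest other 27) and KDI_EX vs HFD (12; 1 gene, highest other 1391), and where the count was 0 the splits say nothing, in DR vs HFD (100; highest other 20), KDI vs HFD (100; highest other 1) and EX vs HFD (100; highest other 3).

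Among 86 groups of libraries behind the printed levels, 8 held a library far from the others, and 4.3 were expected by chance; each value below is the gap to the nearest library divided by the range of the group. Saa3 in nerve SD replicate 4 was 5.55 with the next at 4.33 (0.813), and in muscle it was 3.13 in SD replicate 1 with the next at 2.49 (0.757) and 2.51 in DR replicate 6 with the next at 2.35 (0.705). Tph2 in muscle SD replicate 1 was 5.50 with the next at 3.82 (0.819). Fasn in muscle SD replicate 6 was 12.48 with the next at 11.24 (0.57). Cyp1a1 in muscle HFD replicate 3 was 5.76 with the next at 5.56 (0.63). The skeletal muscle score of nerve EX replicate 5 was 4.06 with the next at -0.50 (0.807), and the adipocyte score of muscle KDI_EX replicate 5 was 0.75 with the next at -0.32 (0.638).

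Effects that differed between the tissues by a test of the difference, nerve minus muscle, were those of Gm11837 (-0.60) on HFD vs SD, Acadsb (0.52) and Oxct1 (0.61) on KD vs SD, and Sctr (1.12) on KDI_EX vs HFD.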

How the results depend on the processing

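The exact tests of list scores, quantile normalisation, the leaving out of libraries that stood apart and the pooled ketogenic arms were chosen only after the data were seen. Of 228 counts and summary values under an alternative, 112 stayed within bounds and 116 moved. Among those that moved, r in muscle changed sign when the HFD libraries were split, from -0.276 to 0.0721 for KDI and from -0.309 to 0.0681 for EX. Named values past the threshold numbered 62, where a gene can count in several comparisons and in both tissues. Of these, 58 kept their call with quantile normalisation, 50 with no filter on low values, 54 with library quality weights, 53 with marker scores as covariates, 53 without the libraries that stood apart and 25 with only the groups compared, and none changed direction. Of 142 other named values, 4 passed with weights and 9 with covariates. The negative binomial tool and the alternative library scaling that were planned were not run because the files hold no counts. Depth is unknown, so its limits could not be measured. On simulated data of nerve HFD vs SD with 200 changed genes, 81.4% of changes of log2 0.5 were recovered and 36.4% of log2 0.25. These shares need not hold for the real data. Simulated changes of log2 2 were recovered at 99.8%, while the real nerve changes of Saa3 (2.27) and Tph2 (2.53) were not called. Fits with only the groups compared hold fewer libraries and estimate the spread from those groups alone. For the other moves the cause was not tested.

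With library quality weights the called genes were 3787 in nerve HFD vs SD, 44 in DR vs HFD, 8 in KDI vs HFD, 857 in EX vs HFD, 2 in KDI vs DR, 1 in the interaction and 98 in the pooled ketogenic arms, and in muscle 257 in HFD vs SD, 223 in KD vs SD, 54 in DR vs HFD, 18 in KDI vs HFD, 197 in KDI vs DR and 244 in the pooled arms. Tissue differences with weights numbered 3072 in HFD vs SD, 78 in KD vs SD, 178 in DR vs HFD, 963 in EX vs HFD and 3 in KDI_EX vs HFD.

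With marker scores as covariates the called genes were 549 in nerve HFD vs SD, 5 in KD vs SD, 204 in DR vs HFD, 208 in KDI vs HFD, 4 in EX vs HFD, 137 in KDI_EX vs HFD, 7 in KDI vs DR and 226 in the pooled arms, and in muscle 7 in HFD vs SD, 97 in KD vs SD, 7 in DR vs HFD, 24 in KDI vs HFD, 1 in EX vs HFD, 10 in KDI_EX vs HFD, 34 in KDI vs DR and 219 in the pooled arms. Called lists with these covariates were 6 in nerve HFD vs SD, 5 in EX vs HFD and 12 in the interaction, and 9 in muscle KDI vs HFD.

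Quantile normalisation gave 1 gene in nerve HFD vs SD. No filter on low values gave 2 in nerve HFD vs SD, 1 in nerve DR vs HFD and 11 in muscle KDI_EX vs HFD. Without the libraries that stood apart (nerve EX replicate 5 and KDI_EX replicate 7, muscle DR replicate 1 and KDI_EX replicate 6) it was 1 in nerve HFD vs SD, and in muscle 5 in HFD vs SD, 1 in DR vs HFD and 36 in KDI_EX vs HFD. With only the groups compared, limma called 0 in nerve KD vs SD, 5 in DR vs HFD, 0 in KDI_EX vs HFD and 1 in KDI_EX vs KDI, and in muscle 1 in HFD vs SD, 105 in KD vs SD, 0 in DR vs HFD, 2 in KDI vs HFD, 2 in KDI_EX vs HFD and 3 in KDI vs DR.

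With an estimated correlation in camera, 0 lists were called in any of the 9 comparisons of either tissue, with fry it was 0 in each, and with exact permutation of list scores 0 in each comparison of 2 groups. Of 223 called lists in the 9 comparisons, leaving out the single library that mattered most shrank the difference of mean scores by over 1.5 times in 128 and changed its sign in 7. With the HFD libraries split so that each effect used its own, r between the HFD effect and the effect of the intervention was -0.196 for DR, -0.124 for KDI, -0.0573 for EX and -0.13 for KDI_EX in nerve, and -0.336, 0.0721, 0.0681 and -0.256 in muscle.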

Other observations

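Pooling the ketogenic arms, the comparison of KD with HFD, and the test on branched-chain amino acid genes were chosen only after the results were seen. When KD, KDI and KDI_EX were pooled against the other 4 groups, limma called 48 genes in nerve (16 higher, 32 lower; n = 21 and 26) and 143 in muscle (68 higher, 75 lower; n = 20 and 29). In nerve, the neighbouring imprinted genes Zim1 (chromosome 7, 6671269 to 6696450) and Peg3 (6703892 to 6730431) were higher, by 0.94 ± 0.13 (adjusted p = 4.95e-05) and 0.44 ± 0.10 (adjusted p = 0.0237). Cldn11, a tight junction claudin, rose by 0.27, while Orm1, an acute-phase plasma protein, fell by 1.08 (adjusted p = 0.0154), Tph2 fell by 1.78 ± 0.28 (adjusted p = 0.000608) and Saa3 fell by 1.39 ± 0.25 (adjusted p = 0.00388). Most of these 2 differences came from HFD and EX: Tph2 lay at 8.19 and 8.24 there, 5.67 in SD, 6.05 in DR and 4.91 to 5.46 in the ketogenic arms, and Saa3 at 6.71 and 6.65, 4.44, 4.60 and 4.06 to 4.32. The mean of Peg3 was lower in KD (11.89) than in EX (11.95) and that of Cldn11 lower in KD (8.12) than in HFD (8.13).

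In muscle, Fbp2 rose by 0.88 ± 0.07 (adjusted p = 5.78e-12) and Actc1 by 0.91 ± 0.11 (adjusted p = 2.83e-07) in the pooled arms. Chrna2, a nicotinic receptor subunit, was higher by 0.71, Lgr6, a receptor of the R-spondin family, by 0.74 and Igfn1, a sarcomeric protein, by 0.75. For Chrna2 and Lgr6, HFD and EX lay further from SD and DR than from KD: Chrna2 lay at 6.15 in SD, 6.28 in DR, 7.16 in HFD, 7.10 in EX and 7.28 to 7.56 in the ketogenic arms, and Lgr6 at 5.23, 5.43, 5.98, 5.93 and 6.28 to 6.48. Igfn1 was 8.74 in KDI and 8.70 in DR. Orm1 (-1.02), Hp (-0.99), Fasn (-0.87) and Slc2a4 (-0.29) fell, and Acadl (0.42) and Acot2 (0.61) rose. HFD and EX lay between the low-fat groups and the ketogenic arms for both, Acadl at 13.58 and 13.57 (SD 13.30, DR 13.36, ketogenic arms 13.85 to 13.90) and Acot2 at 10.54 and 10.47 (SD 10.17, DR 10.31, ketogenic arms 10.90 to 11.08). Hp was not lower in each ketogenic arm, with 10.98 in KDI against 10.37 in SD and 10.39 in DR, and its difference came in large part from HFD (12.03) and EX (11.66). With marker scores as covariates Hp was at -0.57 (adjusted p = 0.000477; range over the alternatives 0.000477 to 0.0434). Of 20 adipocyte markers 4 were positive in the pooled arms of muscle (median -0.22, adjusted p = 0.000417, and adjusted p = 0.979 with an estimated correlation), and none of 12 slow fibre genes was (median -0.32, adjusted p = 0.00353, and adjusted p = 0.979 with an estimated correlation). The covariates hold both scores, so which of them accounts for the smaller change of Hp stays open. The count was as large in 1 of 100 splits of the muscle libraries (143 genes, highest other 5) and in 2 of 100 of the nerve libraries (48 genes, highest other 487). Because this pooling was chosen after the results were seen, the splits are not independent evidence for it. In nerve another split called more genes than the real one, so chance cannot be excluded there. The reason for that count was not tested.

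KD compared with HFD gave 6 called genes in nerve and 50 in muscle. In nerve it was 17 with quantile normalisation, 8 with no filter on low values, 48 with library quality weights, 230 with marker scores as covariates and 12 without the libraries that stood apart. In muscle it was 57, 45, 123, 28 (19 of them among the 50) and 54. A fit of only the KD and HFD libraries was not run for this comparison. In nerve, Itgad, a leukocyte integrin subunit (chromosome 7, 128154376 to 128223816), was lower by -3.78 ± 0.74 (adjusted p = 0.0269, lower in 7 of 7 KD libraries) and Serpina3n by -0.57 ± 0.11 (adjusted p = 0.0287, 7 of 7). Itgad lay at 8.425 ± 2.073 in HFD and 4.646 ± 0.119 in KD, so its printed error understates the spread of HFD. Serpina3n lay at 12.04 in KD, 12.16 in SD and 12.22 in DR, against 12.61 in HFD and 12.62 in EX, so HFD and EX stood apart for it. In muscle, Kcnab1 rose by 0.75 ± 0.11 (adjusted p = 0.000194), Dkk3, a secreted protein of the Dickkopf family, by 0.85 ± 0.18 (adjusted p = 0.0103) and Odc1, the enzyme that starts polyamine synthesis, by 0.58 ± 0.13 (adjusted p = 0.0297), and Dgat2, an enzyme of triglyceride synthesis, fell by 1.09 ± 0.22 (adjusted p = 0.00738), each in 7 of 7. With marker scores as covariates Dkk3 (0.64), Odc1 (0.39) and Dgat2 (-0.49) lost their calls (adjusted p = 0.217, 0.401 and 0.122; ranges over the alternatives 0.00395 to 0.217, 0.0127 to 0.401 and 0.00361 to 0.122), and Odc1 (0.44) also with library quality weights (adjusted p = 0.0948). Of 20 adipocyte markers 2 were positive in muscle on KD against HFD and 8 fell adjusted over the list alone (median -0.48, adjusted p = 5.87e-11, and adjusted p = 0.942 with an estimated correlation), and none of 12 slow fibre genes was positive (median -0.90, adjusted p = 7.13e-08, and adjusted p = 0.942 with an estimated correlation). The fall of Dgat2 can come in part from less fat tissue or from fewer slow fibres, since the covariates hold both scores. Lep, itself an adipocyte marker, fell by 2.50 in muscle on KD against HFD (adjusted p = 0.00738) and by 1.39 with marker scores as covariates (adjusted p = 0.00166; range over the alternatives 0.00166 to 0.0121), which leaves the same 2 sources open.

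A hypothesis is that branched-chain amino acid breakdown is reduced by the ketogenic diet in muscle and that this recurs after a switch from HFD. Its list of 23 genes was written after called members had been seen, so its lower score on KD than on SD (-0.21, exact permutation p = 0.000466; 7 of 23 members fell) is not independent evidence. In KDI against HFD the score differed by -0.04 (exact permutation p = 0.421), with 18 of 23 members below zero, and in nerve on KD by -0.02 (exact permutation p = 0.692). The recurrence therefore stays open, and a smaller effect after the switch may exist that 7 libraries per group do not resolve.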
